A study of Schmidtea mediterranea with 3 samples.

How the data were processed

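RNA was measured in 3 libraries of the planarian flatworm Schmidtea mediterranea, clonal strain CIW4, with 1 library per group. X1 held stem cells (neoblasts) sorted on Hoechst dye for their high DNA content. X2 held the progeny of the stem cells, sorted in parallel as a low-DNA side population. The irradiated library was made from whole animals 7 days after a lethal dose of gamma rays, which removes the stem cells, and stands for differentiated tissue. Per the labels' protocols, cells from several sorts were pooled for each sorted sample, and Illumina TruSeq libraries were made after polyA selection. Each sorted library is therefore a pool, and no group has a replicate.

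The deposited table gives 3 values per assembled transcript in cRPKM, which the authors' column headers name and which stands here for a corrected RPKM, reads scaled to transcript length and library size. The correction, the aligner, the counting tool and the assembly method are not given in the sources used here. The table holds 20214 transcripts, and in each of them at least 1 library reached 2 cRPKM, so a minimum had been set before deposit. The deposited transcript sequences number 48833, and the 28619 without a row in the table were not analysed here. Sequences were used for transcript length and base composition only. Median length was 1092 bases and median GC content 33.6%. No reference genome was used here, so no genome coordinates are given.

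Gene names are the mouse best blast hits that the deposited table pairs with the transcripts. A mouse name was present for 14371 transcripts (71.1%), covering 7907 mouse genes, and 10520 of them also carried the authors' rank among the transcripts hitting that gene. A name is a similarity, not an orthology call. Some ranked names stood far down, such as Mrc1 and 1 Ddx4 transcript at rank 12 and Kcnh3 at rank 11, and these transcripts may be relatives of the named gene. Names without a rank include some that were attached to many transcripts, such as Rhox8 on 125 and Mlph on 90, and are marked in the text as unranked. Transcripts of one name can be fragments, alleles or paralogs, and reads shared between near-identical transcripts make their single levels uncertain.

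Depth was read from the spacing of low values. In transcripts under 600 bases, values between 0.05 and 1 cRPKM fell within 0.15 of a whole read for 77.2% of values in X1 and 75.2% in the irradiated library, where chance gives 30%. This held for 36440000 reads in X1 and 35400000 in the irradiated library, with 50 bases taken off each length. For X2 the best step score, which is higher when values lie closer to whole reads, was 0.0756, with 75 bases taken off. It was 0.678 for X1 and 0.62 for the irradiated library. At the read number of that X2 score, but with 50 bases taken off, the share was 28.1%. The depth of X2 is therefore unknown, and what set this column apart is not given in the sources used here. At the median length and the X1 depth, 1 cRPKM rests on 38 reads, for a counting error of 16.2%. Values times length, with 50 bases taken off, summed to more than all reads, 115% in X1 and 116% in X2 and the irradiated library. The depths and this error are therefore approximate. These errors cover counting only. X2 was listed at exactly 0 for 901 transcripts, against 246 in X1 and 67 in the irradiated library, and no fold is given against a value of 0.

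From the table, log2 ratios of (cRPKM + 0.5) were computed for 3 comparisons, X1 against irradiated, X2 against irradiated and X1 against X2. Folds printed are on this scale, which understates the difference of low transcripts. Transcripts entered a comparison when the larger value was at least 1 cRPKM, and those at least 2-fold apart were counted. A transcript was assigned to a library when its value there was at least 2-fold above both others. With 1 library per group no test between conditions can be made, no p-value is given, and the difference has no replicate check in any comparison. The design was fixed without knowing the unit, and its alternative normalizations for counts do not apply to RPKM.

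For 20 gene lists, fixed by name pattern before the data were examined, the median log2 ratio was set against 10000 random lists of the same size, drawn from the transcripts with a mouse name and matched on mean log2 level in 20 bins. The percentile of the list describes these libraries and is not a test between conditions. Transcripts were drawn singly, so several transcripts of 1 mouse gene count separately. In X1 against irradiated the neuron list had 369 transcripts of 159 mouse genes, and the epidermal progeny list 17 of 5. The lists were DNA replication, mitosis and cell cycle, germline and piRNA factors, Polycomb and COMPASS complexes, chromatin remodelling complexes, splicing factors, ribosomal proteins, ribosome biogenesis, proteasome, oxidative phosphorylation, DNA repair, histones, epidermal progeny markers, muscle, neurons, cilia, gut and digestion, extracellular matrix and adhesion, stress and apoptosis, and signalling ligands and receptors. Some transcripts belong to more than 1 list. The histone list also held 1 transcript named H47, which its name pattern caught although H47 is not a histone.

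Genes named in the text follow a rule set before the data were examined. Per comparison these were the 8 highest and 8 lowest log2 ratios among named transcripts whose higher value reached the median, and per list the member with the highest mean and the 2 with the largest absolute ratio. The 5 highest transcripts of each set assigned to 1 library were added, as were piwi, Pcna, Mcm2 to Mcm7, ribonucleotide reductases, cyclin B, Cdk1, vasa, bruno-like, nanos and amidinotransferase names wherever they matched. A name held by several transcripts is given by its highest one, or by the one the rule picked. The numbers of transcripts with the same name were 2 for Actb, Celf6, Ctnnb1, Fzd8, Hpgds, Kcnh3, Kif20a, Mcm2, Mcm3, Msh6, Myh4, Myh6, Nbn, Orc1, Pcna, Plk1, Polr1a, Rad21, Rpl32, Rpl36a, Rps14, Rrm2, Rrm2b, Smarcc1, Wfdc6b, Ybx2 and mt-Co3; 3 for Chat, Ddx4, Hist2h2aa1, Lmnb1, Mmp19, Piwil1, Pold1, Psmc1, Tuba1c and mt-Co1; 4 for Cdk1, Elavl3, Lipa and Pigr; 5 for Celf4, Ctsl, Dkc1, Gatm and Ifit1; 6 for Col5a1, Col7a1, Hspa8, Odc1 and Rbbp4; 7 for Grn; 10 for Mrc1; 13 for Mll2; 18 for Snhg11; 26 for Wdr66; 33 for AC122027.1; 50 for Mylk4; 90 for Mlph. Other names under this rule had 1 transcript.

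The authors' class labels (stem cell specific, stem cell enriched, stem cell and progeny, progeny specific, differentiated specific) were used as deposited. The ratio and list functions were tested on simulated data drawn at the depth and levels of X1 against irradiated over 20214 transcripts. All 100 transcripts with a true 4-fold difference and all 100 with a true 8-fold difference were recovered, 0.0509% of unchanged transcripts were called at least 2-fold apart, and 7 of 100 random lists of 60 fell outside the central 95%. The simulated data held counting noise only, with no spread between libraries or animals. True differences were placed only in named transcripts above a minimum of expected reads, and X2 was not simulated. Alternatives covered the pseudocount, the floor, the fold, the scaling, transcript length, the choice among transcripts of 1 name and the matching of random lists. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba and matplotlib 3.10.9.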

Results

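The 3 libraries profiled the planarian stem cell lineage by polyA RNA sequencing. X1 contained sorted stem cells (neoblasts, the dividing cells of the adult animal), X2 contained their sorted progeny, and the irradiated library contained the tissues of whole animals without stem cells. Each group had 1 library, so no value below has a replicate error and no difference could be tested against a spread. The spacing of low values gave 36440000 reads for X1 and 35400000 reads for the irradiated library, while the depth of X2 could not be read. Of 20214 transcripts, 15943 reached 1 cRPKM in X1, 16981 in X2 and 18886 in the irradiated library. One transcript, an unranked hit to Nkx2-1 outside the naming rule and named after its values were seen, took 22.8% of the column sum in X1, 23.5% in X2 and 27.3% in the irradiated library.

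**Figure D1:**
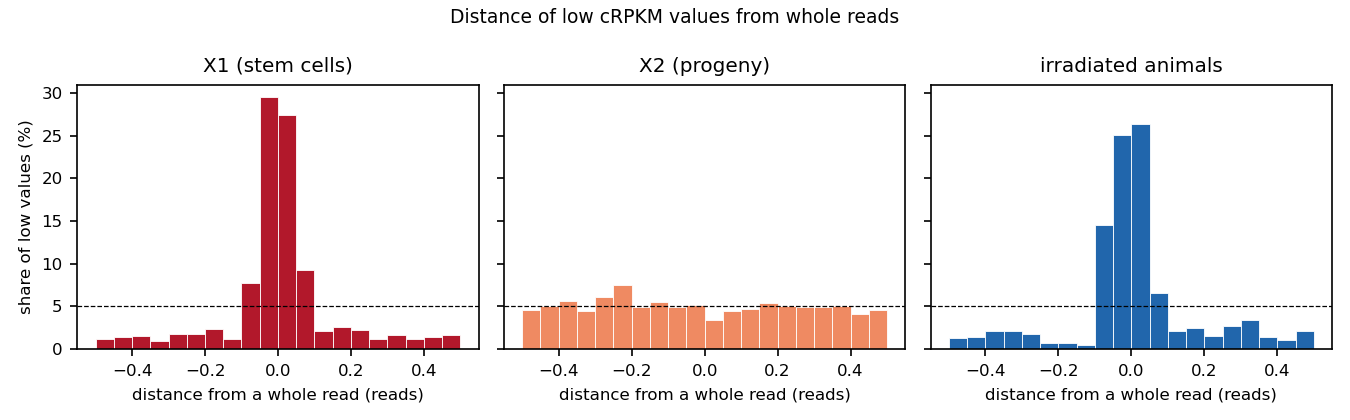
Distance of low values (0.05 to 1 cRPKM, transcripts under 600 bases) from the nearest whole read in each of the 3 libraries, as a share of values per bin of 0.05 reads. The dashed line marks an even spread. Values gather at 0 in X1 and the irradiated library (77.2% and 75.2% within 0.15 reads) and lie evenly in X2 (28.1%). All panels have 50 bases taken off each length, while the X2 read number came from a setting with 75.

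Levels in X1 and X2 resembled each other more than either resembled the irradiated library. Across transcripts, which are not independent replicates, the Pearson correlation of log2 levels was 0.84 between X1 and X2, 0.56 between X2 and the irradiated library and 0.46 between X1 and the irradiated library. Spearman coefficients were 0.82, 0.55 and 0.42. Among transcripts of at least 5 cRPKM in either library these Pearson values were 0.73, 0.39 and 0.27.

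The comparison of X1 with irradiated animals asks which transcripts mark the stem cells. Most DNA replication transcripts and all 3 transcripts named Piwil1 were far higher in X1, and most transcripts of the muscle, gut, neuron and matrix lists were lower. Piwil1, an Argonaute protein that binds piRNAs, stood at 1816 cRPKM in X1 and 11.1 in irradiated animals, a 156-fold difference for the highest of 3 transcripts. Pcna, the sliding clamp of DNA polymerase, stood at 515 against 3.02 cRPKM, while its second transcript was nearly level at 9.86 against 9.41, and the linker histone Hist1h1b stood at 283 against 1.04. At the other end, Cnn3, an actin-binding calponin, had 10.4 cRPKM in X1 and 1035 in irradiated animals.

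Among 19977 transcripts past the floor, 4710 were at least 2-fold higher in X1 and 8319 at least 2-fold lower. The median log2 ratio was -0.52, and every ratio lies that much higher when the median is set to 0. Of the transcripts at least 2-fold apart, 36.2% were higher in X1 with the values as deposited and 48.4% with the median at 0, where the counts were 6359 and 6778. Of the 20 gene lists, 12 had medians above the central 95% of matched random lists and 6 below. Sorted, dissociated cells were set against whole animals here, and that difference in handling goes with the group. The animals had been lethally irradiated 7 days before, and no unirradiated tissue was measured. Any response to irradiation therefore goes with the group as well, also in X2 against irradiated.

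DNA replication stood highest, with 54 of 65 transcripts at least 2-fold higher in X1, 3 lower and a median log2 ratio of 3.40. Subunits of the replicative helicase showed this throughout, with Mcm2 at 213 against 1.25 cRPKM, Mcm3 at 257 against 2.07, Mcm4 at 176 against 0.9, Mcm5 at 166 against 1.27 and Mcm7 at 320.4 against 2.15. Mcm6 kept a higher level in irradiated animals, 28.3 cRPKM against 303 in X1. The ribonucleotide reductase transcripts Rrm1 and Rrm2b stood at 488 and 579.9 cRPKM in X1 and at 13.03 and 14.4 in irradiated animals. The 2 transcripts named Rrm2 reached at most 3.81 cRPKM in any library. In the mitosis list 57 of 87 transcripts were higher and 15 lower, with a median of 2.15. Its cyclin B members Ccnb1 and Ccnb2 had 92.4 and 118 cRPKM in X1 against 1.27 and 0.84. The kinase Cdk1 had 49.2 against 0.92 for the highest of 4 transcripts, of hit rank 7, and 37.9 against 0.31 for the one of rank 1. Rad21, a cohesin subunit and the most abundant member, differed 8.91-fold. Of 68 DNA repair transcripts, 55 were higher and 5 lower, with a median of 2.44. Ung, which removes uracil from DNA, had 334 against 10.96 cRPKM, Nbn differed 74.9-fold and the exonuclease Exo1 42.7-fold.

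The germline and piRNA list had 20 of 36 transcripts higher, 9 lower and a median of 2.06. Ddx4 (vasa, an RNA helicase of germ cells) stood at 598 against 28.7 cRPKM for the highest of 3 transcripts. The lowest, of hit rank 12, stood at 48.2 against 28.3. Nanos1, an RNA-binding regulator of germ cells, stood at 13.4 against 0.59. The bruno-type transcripts went both ways. Celf4 had 369 cRPKM in X1 and 7.13 in irradiated animals for the highest of 5 transcripts, 3 of the 5 were at least 2-fold lower in X1, and Celf3 had 0.36 and 15.1. Polycomb and COMPASS complexes had 32 of 57 transcripts higher (median 1.24), and chromatin remodelling complexes 45 of 86 (median 1.05). The histone-binding protein Rbbp4, shared by several such complexes, differed 81-fold in its most divergent transcript, and the deacetylase Hdac2 had 922 against 98.98 cRPKM. An unranked hit to Mll2 was the most abundant member of the Polycomb and COMPASS list and went the other way, with 37.6 cRPKM in X1 and 1537 in irradiated animals. Of 23 histone transcripts, 13 were higher and 5 lower, with a median of 2.18. Among transcripts of at least 500 bases the histone median was 0.46, inside the random range. Replication-dependent histone mRNAs commonly lack a polyA tail, and the libraries were polyA-selected.

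Transcripts for making and processing RNA and protein were also higher in X1. Of 92 ribosomal protein transcripts, 65 were higher and 9 lower (median 2.62), and Rpl27a, the most abundant, had 4401 against 620.5 cRPKM. Of the 9 lower ones, 4 were listed at 0 in both X1 and X2, and 8 of the 92 had a GC content of 55% or more. Ribosome biogenesis had 58 of 72 higher (median 2.39), led by the polymerase I subunit Polr1a at 95.3 against 0.73 cRPKM, an unranked hit. Splicing factors had 108 of 149 higher (median 1.81), including Prpf4 at 1152 against 170.0 cRPKM. The proteasome list had 39 of 53 higher (median 1.60), with the base ATPase Psmc1 differing 2.9-fold. Oxidative phosphorylation had 42 of 61 higher (median 1.27), with the ATP synthase subunit Atp5b at 1014 against 220.3 cRPKM.

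Differentiated tissue lists lay on the other side. Gut and digestion had 71 of 89 transcripts lower in X1 and 4 higher, with a median of -3.41. Its lysosomal protease Ctsl had 45.5 cRPKM in X1 and 3331 in irradiated animals, and the lysosomal lipase Lipa 19.9 and 1662. Muscle had 91 of 125 lower and 6 higher (median -2.69), with the myosin heavy chain Myh4 at 8.74 against 799 cRPKM and the actin-binding protein Tagln at 10.1 against 912. Extracellular matrix and adhesion had 196 of 248 lower (median -2.73), with Col5a1 at 28.3 against 543 cRPKM. Neurons had 304 of 369 lower (median -2.52), with the channel Kcnh3 at 3.37 against 232 cRPKM. Signalling ligands and receptors had 110 of 188 lower (median -1.50, percentile 0.07), and that median was inside the random range, at percentile 3.64, with a floor of 5 cRPKM. Ctnnb1, the most abundant member, was nearly level at 65.3 and 68.2 cRPKM. In the cilia list 79 of 133 were lower and 8 higher (median -1.33). Its largest ratios were those of alpha tubulins, which build microtubules in all cells, with Tuba1c, an unranked hit, at 4158 against 25.9 cRPKM. Inside the random range were the stress and apoptosis list (median -0.32, percentile 88.22) and the epidermal progeny list (median -0.45, percentile 77.18). With the median of all transcripts at 0 these became 0.20 and 0.07. The chaperone Hspa8 had 5285 cRPKM in X1 and 6615 in irradiated animals.

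**Figure D2:**
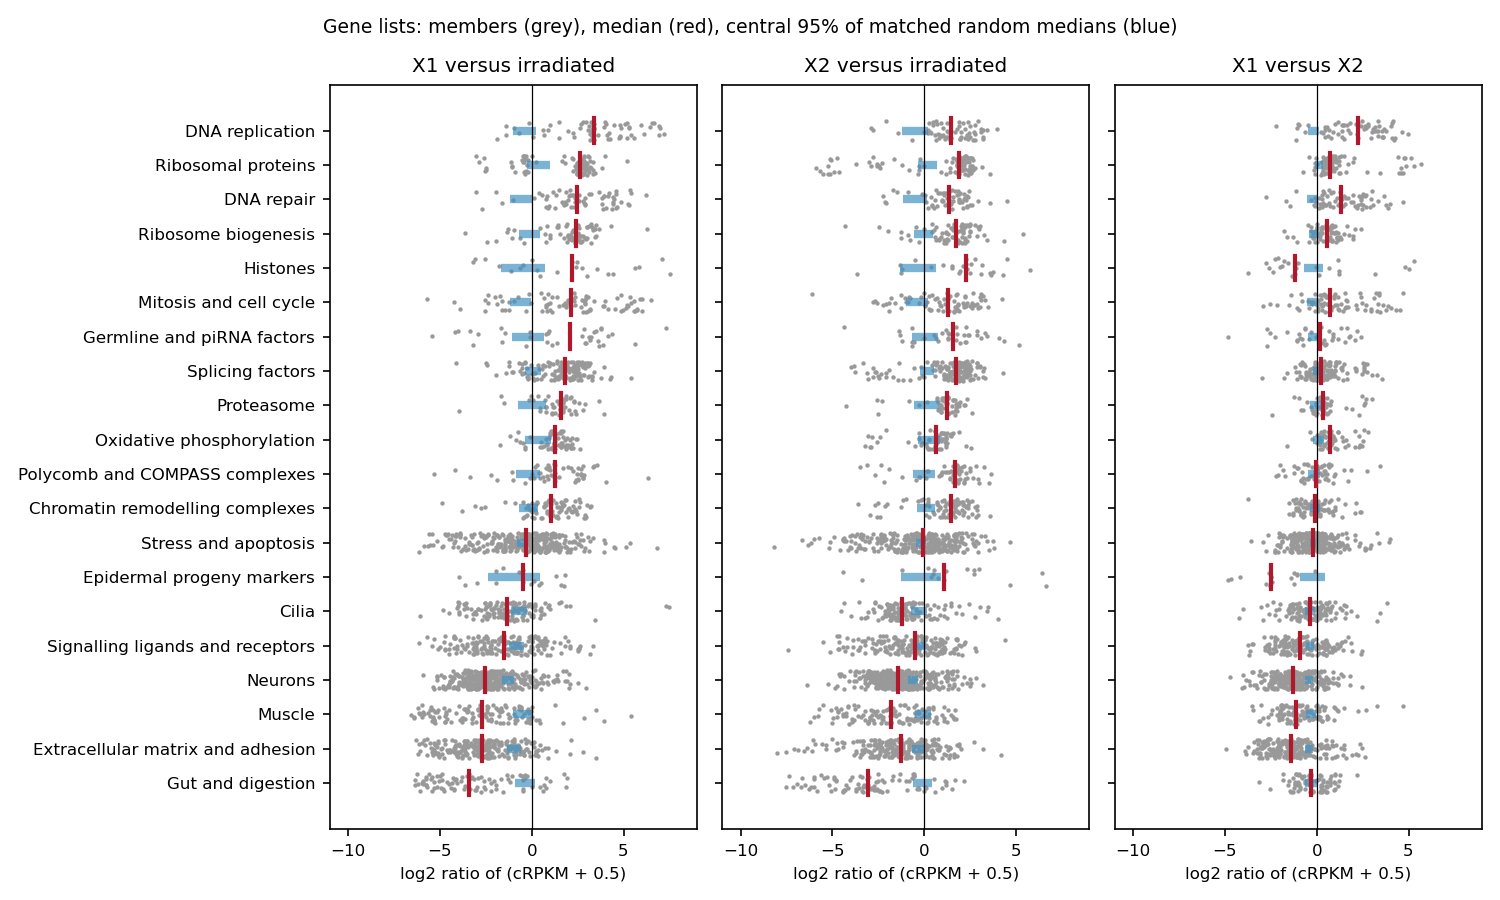
Log2 ratio of (cRPKM + 0.5) for the transcripts of 20 gene lists (grey points) in the 3 comparisons, with list medians (red) and the central 95% of medians of matched random lists (blue bars), from 1 library per group. DNA replication has the highest median in X1 against irradiated (3.40) and gut and digestion the lowest (-3.41).

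X2 against irradiated animals asks the same of the cells labelled as stem cell progeny. Whether this low-DNA gate also held stem cells was not tested. The highest ratios belonged to transcripts at a few cRPKM or less in irradiated animals. Gatm, a glycine amidinotransferase whose planarian relatives mark late progeny, had 437 cRPKM in X2, 14.7 in X1 and 3.85 in irradiated animals for the highest of 5 transcripts. Trp63, of the p53 family of transcription factors, had 176 cRPKM in X2 and 1.71 in irradiated animals. A group of unranked hits was higher still, with Chfr at 1869 against 2.18 cRPKM, Snhg11 at 1788 against 2.13, Mylk4 at 1734 against 2.16 and Wdr66 at 1057 against 0.64. Snhg11, Mylk4 and Wdr66 were names shared by 18, 50 and 26 transcripts. On the lower side stood Mrc1, a mannose receptor, with 3.26 against 3548 cRPKM, and Coro2a, an unranked hit, with 0.21 against 257. Wfdc6b, at 876 cRPKM in irradiated animals, was listed at 0 in X2.

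Among 19900 transcripts past the floor, 5124 were at least 2-fold higher in X2 and 7097 lower, with a median log2 ratio of -0.18. Of the transcripts at least 2-fold apart, 41.9% were higher in X2 as deposited. With the median at 0 this was 47.8%, with counts of 5908 and 6461. The depth behind the X2 values is unknown, so no counting error can be given for them. Without the transcripts listed at 0 in X2 the lower set numbered 6275, an alternative chosen after seeing the data. Of the lists, 12 lay above the central 95% of random lists and 5 below.

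Lists for division, RNA regulation and chromatin lay above the random range in X2 as well. DNA replication had 41 of 63 transcripts higher and 4 lower (median 1.43), with Mcm7 at 41.3 against 2.15 cRPKM and Orc1, of the origin recognition complex, at 105 against 15.1. Mitosis had 47 of 81 higher (median 1.31), with the kinase Plk1 at 60.3 against 2.76 cRPKM, and DNA repair had 45 of 66 higher (median 1.35). Germline and piRNA factors had 23 of 36 higher and 4 lower (median 1.54), with Piwil1 at 419.8 cRPKM and Ddx4 at 133. Polycomb and COMPASS complexes had 40 of 57 higher (median 1.67) and chromatin remodelling 55 of 86 (median 1.46), including Smarcc1 at 309.7 against 25.9 cRPKM. Histones had 20 of 26 higher (median 2.25), with Hist1h2bf at 43.4 against 1.45 cRPKM. Splicing factors had 109 of 149 higher (median 1.73), ribosome biogenesis 53 of 73 (median 1.73) and the proteasome 32 of 51 (median 1.24). Dkc1, a pseudouridine synthase of the nucleolus, had 402 cRPKM in X2 and 9.25 in irradiated animals.

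Ribosomal proteins had 63 of 92 transcripts higher and 22 lower, with a median of 1.89. Of these 92 transcripts, 18 were listed at 0 in X2, and 8 of these had a GC content of 55% or more. Without the zeros, 4 of 74 were lower. Of the 2 transcripts named Rpl32 and the 2 named Rpl36a, 1 each was listed at 0, while the others had 1642 and 2683 cRPKM in X2, values given after they were seen. Rps14, the most abundant, had 3256 cRPKM in X2 against 764. Oxidative phosphorylation had 18 of 61 higher and 8 lower, with a median of 0.66 inside the random range (percentile 89.38), and 8 of its transcripts were listed at 0 in X2. Without these, 0 of 53 were lower. The epidermal progeny list, 17 transcripts of 5 mouse genes, had 9 higher and 3 lower (median 1.05, percentile 98.94). Its members did not go together, since Odc1, which makes polyamines, had 1203 against 922 cRPKM and 1 Gatm transcript had 0.06 against 11.5.

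Gut and digestion was lowest, with 66 of 89 transcripts lower and 6 higher (median -3.08). Ctsl had 36.3 cRPKM in X2 and 3331 in irradiated animals, and Lipa 8.53 and 1662. Muscle had 78 of 125 lower (median -1.79), neurons 236 of 374 (median -1.41), extracellular matrix and adhesion 141 of 250 (median -1.24) and cilia 75 of 133 (median -1.19). Cnn3 differed 63.3-fold, Kcnh3 82-fold and Mmp19, a matrix protease, 255-fold. Some members of these lists were higher in X2. Elavl3, an unranked hit to a neuronal RNA-binding protein, had 1520 cRPKM in X2 and 338 in irradiated animals, and the nuclear lamin Lmnb1, part of the matrix and adhesion list by its pattern, 605 and 90.4. Signalling (median -0.52, percentile 6.89) and stress and apoptosis (median -0.06, percentile 78.90) lay inside the random range, and the stress median was 0.12 with the median of all transcripts at 0.

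The comparison of X1 with X2 asks how stem cells and their progeny differ within the lineage. Of 65 DNA replication transcripts, 47 were at least 2-fold higher in X1 and 4 higher in X2, 4 of the 5 Gatm transcripts and some neural transcripts were higher in X2, and the medians of the chromatin lists were near 0. X1 was sorted for high and X2 for low DNA content, so the stage of the cell cycle goes with the sort. For the replication, mitosis and repair lists it cannot be told apart from a difference between stem cells and progeny. A subtraction of X1 and irradiated values from the X2 column was not excluded. It would by itself raise the X1 to X2 ratios of transcripts high in X1 and lower the X2 to irradiated ratios, and no ratio here was corrected for it. Prim1, a DNA primase subunit, had 64.5 cRPKM in X1 and 1.57 in X2, a 31.4-fold difference, and the kinesin Kif20a, an unranked hit that acts in cell division, differed 26.1-fold. Gatm differed 28.8-fold in the other direction. Chat, which makes acetylcholine, had 1.74 cRPKM in X1 and 58.03 in X2, near the 73.7 of irradiated animals. The matrix gene Col7a1 had 1.94 in X1 and 73.4 in X2.

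Of 18144 transcripts past the floor, 2593 were at least 2-fold higher in X1 and 4809 higher in X2, with a median log2 ratio of -0.27. Of the transcripts at least 2-fold apart, 35% were higher in X1 as deposited and 49.9% with the median set to 0, where the counts were 3521 and 3535. With a floor of 5 cRPKM, 2994 were higher in X2. Of the 20 lists, 8 lay above the central 95% of random lists and 6 below.

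DNA replication had 47 of 65 transcripts higher in X1 and 4 higher in X2 (median 2.23). Pcna stood at 515 against 29.6 cRPKM, with its second transcript the other way at 9.86 against 21.6, Mcm2 at 213 against 11.6, Rrm1 at 488 against 88.0 and Pold1, the catalytic subunit of polymerase delta, at 40.7 against 1.18. DNA repair had 38 of 66 higher (median 1.33), with Msh6, of mismatch repair, at 29.0 against 1.38 cRPKM. Mitosis had 37 of 85 higher (median 0.72), with Ccnb1 at 92.4 against 5.23 cRPKM. The highest Cdk1 transcript, of hit rank 7, stood at 49.2 against 4.14, and the one of rank 1 at 37.9 against 1.18. Ribosomal proteins had a median of 0.72 with 28 of 86 higher and 0 lower. Oxidative phosphorylation had a median of 0.70 and ribosome biogenesis 0.54, with 19 of 61 and 17 of 72 higher. Without the transcripts listed at 0 in X2, 16 of 74 ribosomal protein and 11 of 53 oxidative phosphorylation transcripts were higher, and the medians were 0.68 and 0.62. The medians of splicing factors (0.25) and the proteasome (0.33) were smaller and no longer outside the random range without the transcripts listed at 0 in X2, at percentiles 97.01 and 97.43.

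Germline and piRNA factors were split, with 9 of 36 transcripts higher in X1, 8 higher in X2 and a median of 0.16 inside the random range (percentile 88.01). Piwil1 had 1816 cRPKM in X1 and 419.8 in X2 for its highest transcript, and the other Piwil1 transcripts had 1104 against 619 and 771 against 615. Ddx4 had 598 against 133 cRPKM for its highest transcript and 48.2 against 93.3 for its lowest, of hit rank 12. The highest Celf4 transcript had 369 against 126 cRPKM, and the 4 others were lower in X1 than in X2, 2 of them at least 2-fold. Nanos1 had 13.4 against 2.13 cRPKM, Celf3 0.36 against 23.6 and Celf6 0.5 against 6.07. With 1 transcript per name the list median was 0.59 and at percentile 99.04. Polycomb and COMPASS complexes (median -0.02, percentile 75.26) and chromatin remodelling (median -0.10, percentile 54.31) lay inside the random range, as did cilia (-0.36), gut and digestion (-0.32) and stress and apoptosis (-0.21). With the median of all transcripts at 0 the first pair became 0.26 and 0.17, and stress and apoptosis 0.06. Rbbp4 had 414 against 309.3 cRPKM and Hdac2 922 against 610.0.

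On the X2 side lay 6 lists. Epidermal progeny markers, 15 transcripts of 5 mouse genes, had 14 higher in X2, 0 higher in X1 and a median of -2.47. Egr4, a zinc finger transcription factor, had 6.94 cRPKM in X1 and 51.1 in X2. Histones had 15 of 26 higher in X2 and 7 higher in X1 (median -1.18), with H47 counted among the 26. Hist1h1b stood at 283 in X1 against 6.82 in X2 and Hist2h2aa1 at 502 against 14.9 for the most divergent of its 3 transcripts, and the most abundant histone, H3f3b, had 1440 against 625. On the X2 side, Hist1h3g had 9.6 against 29.98, and, chosen after their values were seen, Hist1h1c had 128 against 611 and Hist1h4a 236 against 519. Extracellular matrix and adhesion had 138 of 220 higher in X2 (median -1.41), neurons 162 of 264 (median -1.27), muscle 61, with 8 higher in X1 (median -1.14), and signalling 75 of 164 (median -0.90). Fzd8, a Wnt receptor, had 1.06 cRPKM in X1 and 20.4 in X2. The muscle list's largest ratio went the other way, in an unranked hit to Myh6 with 35.8 against 0.92 cRPKM.

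Of the 8 names with the highest X1 to X2 ratios, 6 belonged to transcripts listed at 0 in X2. Among them were hits to the mitochondrial genes mt-Co3, mt-Co1 and mt-Cytb, with 94.8, 93.5 and 44.4 cRPKM in X1 and 119, 122.5 and 57.2 in irradiated animals. All 6 transcripts with mitochondrial names and a 0 in X2 had a GC content of 43.8 to 49.8%, and the 4 others with such names, at 30.5 to 33.7%, were above 0. Ifit1, an unranked hit with a value above 0 in X2, had 69.5 cRPKM in X1 and 0.41 in X2.

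**Figure D3:**
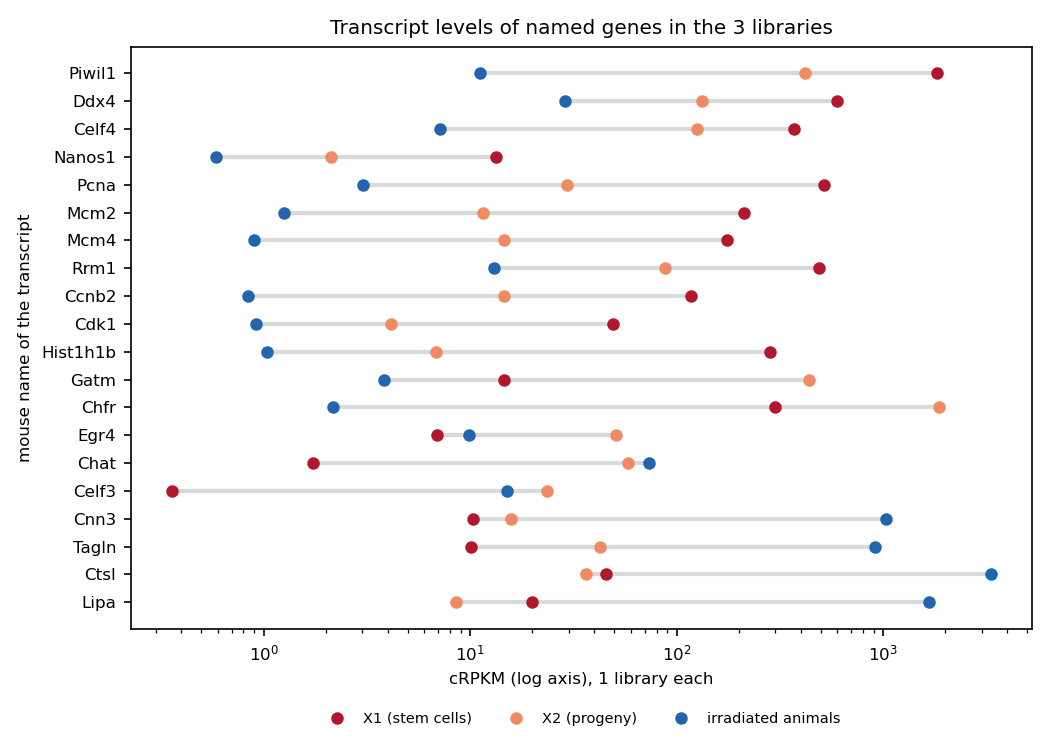
Level in cRPKM (log axis) of 20 named transcripts in X1, X2 and the irradiated library, 1 point per library, taking the highest transcript of each name. Replication and piwi transcripts are highest in X1 (Piwil1 1816 cRPKM), Gatm and Chfr in X2 (437 and 1869), and muscle and gut transcripts in irradiated animals (Ctsl 3331).

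Assigning each transcript to the library where it stood at least 2-fold above both others gave 1563 transcripts for X1, 1326 for X2, 6137 for the irradiated library and 11188 for none. With the median log2 ratio of each comparison at 0 the sets numbered 2317, 1082 and 5216, so the balance of X1 and X2 depends on the scaling. A 4-fold threshold gave 549, 214 and 3394. The X1 set was led by an unranked hit to AC122027.1 at 7129 cRPKM, the Y-box RNA-binding protein Ybx2 at 4725, the unranked Tuba1c at 4158 and the ribosomal proteins Rpl37a at 3656 and Rpl31 at 2768. The X2 set was led by an Hspa8 transcript at 3544 cRPKM, then Chfr, Snhg11, Mylk4 and Elavl3. Actb at 24303 cRPKM, the secreted granulin Grn at 19738, the unranked hits Mlph at 13395 and Pigr at 5401 and the prostaglandin synthase Hpgds at 4649 led the irradiated set. A mouse name was attached to 69.9% of the X1 set, 58.4% of the X2 set and 70.8% of the irradiated set.

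In the authors' deposited table, 539 transcripts were classed as stem cell specific, 817 as stem cell enriched, 791 as stem cell and progeny, 219 as progeny specific and 3424 as differentiated specific, and 14424 had no class. A set of 5-fold ratios between the 3 columns gave the deposited class for 20203 of 20214 transcripts. Of 66 DNA replication transcripts, 32 were classed there as stem cell specific, against 1 of 36 germline and piRNA transcripts, of which 13 were stem cell and progeny. Differentiated specific transcripts included 61 of 89 in gut and digestion and 52 of 127 in muscle. These classes come from the same 3 libraries and are no independent evidence of direction.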

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

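The alternatives without the transcripts listed at 0 in X2, without those of GC 55% or more, rescaled without the highest transcript and with ranked names alone were chosen after seeing the data. Of 219 recomputed counts and correlations, 200 stayed within 1.5 times or 0.05 of their value. With a 4-fold threshold the counts were 2356 higher and 5513 lower for X1 against irradiated, 1679 and 4121 for X2 against irradiated, and 988 and 1530 for X1 against X2, with 549, 214 and 3394 transcripts highest in X1, X2 and irradiated. A 1.5-fold threshold gave 4119 transcripts higher in X1 than X2, and 2621 and 2619 transcripts highest in X1 and X2. These follow from the threshold itself. With a floor of 5 cRPKM, which leaves fewer transcripts, 2994 were lower in X1 than X2, and the Pearson and Spearman correlations were 0.27 and 0.22 for X1 and irradiated, 0.39 and 0.38 for X2 and irradiated, and 0.73 and 0.71 for X1 and X2.

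No list median outside the random range and no named transcript at least 2-fold apart turned its sign. Signs did turn in 18 values of 6 list medians inside the range, among them those given above for the median set to 0, and in 28 values of named transcripts under 2-fold, such as Hspa8 (0.19 with the median at 0) and Ctnnb1 (0.46) in X1 against irradiated. Of 720 recomputed list medians, 708 kept their side of the random range, 7 came inside it and 5 went outside it. Those that came inside were histones in X1 against irradiated with transcripts of at least 500 bases (0.46), signalling in X1 against irradiated with a floor of 5 cRPKM (-1.55), and in X1 against X2 the proteasome (3 alternatives) and splicing factors (2 alternatives). Those that went outside were germline and piRNA factors in X1 against X2 (4 alternatives, up to a median of 0.59) and oxidative phosphorylation in X2 against irradiated with random lists matched on length (percentile 99.81). The cause was not tested. Of 4871 recomputed ratios of named transcripts, 4824 kept their side of 2-fold. Setting the median to 0 shifts all ratios of a comparison by the amount given above and cannot alter a rank within it. Count-based scaling by TMM or DESeq2 size factors was not run, as the values are RPKM, and the gene lists were matched on symbols throughout, as the table gives no gene descriptions, so the alternative with symbols alone was void. No paired analysis was possible because each group has 1 library. The counting error of 16.2% at 1 cRPKM and median length is approximate and covers X1, and the depth behind X2 values is unknown.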

Other observations

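All name families and tests in this part were chosen after the values were seen. Families were formed from the leading letters of ranked mouse names with at least 20 transcripts and compared with matched random lists as above. Of 54 families, 16 lay above and 10 below the central 95% in X1 against irradiated, where chance gives 2.7 if transcripts are independent. Some of them repeat the fixed lists, which already held 40 of 41 Rpl, 41 of 46 Rps and 20 of 21 Col transcripts. Other prefixes, such as AC, BC and Gm, do not name a gene family. Mitochondrial ribosomal proteins, which the fixed lists did not hold, were higher in X1, with 23 of 28 Mrpl transcripts (median log2 2.36) and 18 of 20 Mrps transcripts (median 2.58) at least 2-fold higher and 0 lower. In X1 against X2 the medians were 0.99 and 1.17, with 14 of 28 Mrpl and 14 of 20 Mrps transcripts at least 2-fold higher in X1 and 0 lower. Mrpl12 had 106 cRPKM in X1, 35.3 in X2 and 8.86 in irradiated animals. RNA polymerase subunits (Polr, 28 of 30 higher, median 2.72), general transcription factors (Gtf, 22 of 32, median 1.49) and TBP-associated factors (Taf, 17 of 22, median 1.46) were also higher in X1 than in irradiated animals, while in X1 against X2 the Gtf and Taf medians (0.12 and 0.22) lay inside the random range.

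On the other side, 21 of 25 cytochrome P450 transcripts (Cyp) were at least 2-fold lower in X1 than in irradiated animals and 0 higher, with a median of -3.54, and 20 were lower in X2. Cyp3a57 had 0.65 cRPKM in X1 and 48.6 in irradiated animals. Solute carriers (Slc) had 185 of 310 lower (median -2.06) and Rab GTPases 31 of 51 (median -1.31), with Rab38 at 3.56 against 219 cRPKM. The axonemal dynein heavy chains carry the older symbol Dnahc in the deposited table and so were outside the cilia list. Of 28, 26 were lower in X1 (median -2.55, percentile 2.30), with Dnahc9 at 0.66 against 30.6 cRPKM. Of the progeny specific transcripts in the authors' deposited table, 45.7% had a mouse name, against 66.2% of the stem cell specific ones.

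The X2 column did not fall on whole reads and held more zeros than the others. Whole-read counting at 1 depth is argued against, because the smallest value times length above 0 was 7.51 times below that of X1 and further below that of irradiated, as in a deeper library, while zeros were 3.66 times as many as in X1, as in a shallower one. The X2 step score, with 50 bases taken off each length, was 0.0629, and 20 draws without steps reached 0.0965. A candidate explanation is that the authors subtracted part of the X1 and irradiated values and set negatives to 0. Adding shares of both back gave a whole-read score of 0.131, above 19 shuffled columns (0.0979 to 0.118). The 0.678 of X1 came from a different selection of values, and X1 was not scored under the add-back setting. How high a score a true subtraction would give is therefore unknown, and subtraction and another correction cannot be told apart. The X1 to X2 ratios of transcripts high in X1 would be overstated by a subtraction. A biological source of the zeros was not tested.

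Of 120 transcripts with a GC content of 55% or more, 105 (87.5%) were listed at 0 in X2 and 0 in X1 or irradiated. A loss of GC-rich transcripts from the X2 library cannot be excluded, as zeros made up 3.68% at GC 35 to 40%, 13.2% of the 372 transcripts of GC 45 to 55%, 57.1% at 55 to 60% and 96.7% above. The median log2 ratio of X2 to irradiated was -0.23 at GC 35 to 40%, and 0.82, 1.10 and 1.48 at 40 to 45, 45 to 50 and 50 to 55%. It was -2.29 at 55 to 60% and -2.72 above. The rise up to 55% would go against a graded loss only if these bins held otherwise similar transcripts, which was not tested. A steep loss stays open. Of the 12 transcripts of GC 55 to 60% above 0, 11 were at or above their irradiated level. That count left out the transcripts listed at 0, so it cannot decide the question. Reads of another organism in X1 and irradiated may also account for the GC-rich zeros, as one source would give 1 ratio. Over the GC-rich transcripts at 0 in X2 with at least 10 reads in both other libraries, the log2 ratio of X1 to irradiated had an SD of 0.41. That was 1.45 times its counting error of 0.28. The SD was 2.17 over 11504 transcripts of GC under 45% and above 0 in X2. These lay anywhere within the range of levels of the GC-rich ones. They were not matched in level and had no minimum of reads, so the 2 SDs are not a controlled contrast. A mouse name was present for 28 of 28 transcripts of GC 55 to 60% and 92 of 92 above, against 71.1% of all transcripts. What this says of their origin was not tested. Another organism as the source remains a hypothesis, and no biological explanation was tested. The 796 zeros of X2 at lower GC are not covered, although the 6 mitochondrial names had a median ratio of -0.37, near the -0.32 of the GC-rich set.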
